A study of Oryza sativa with 12 samples.

How the data were processed

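Messenger RNA was measured in leaves of rice (Oryza sativa, cultivar ZH11, called WT here) and of a mutant of PHR2, a MYB-type transcription factor of phosphate (Pi) signalling. Per the labels' protocols, the plants grew on MS medium, and 3-week-old plants were moved to the same medium without Pi, with leaves taken on day 3. The labels give no day for the control libraries. Whether these match the no Pi libraries in day of harvest and in handling is therefore not known. RNA was extracted with a plant RNA kit and made into libraries by standard Illumina protocols, per the labels' protocols. The 12 libraries fall into 4 groups of 3 replicates: WT control, WT no Pi, phr2 control and phr2 no Pi. The series' design text also names mutants of DGP1, which are not analysed here. The labels do not state whether replicates are separate plants or cultures, so every p-value measures only the spread between these libraries, part of which can be technical.

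The authors deposited 1 table of FPKM, fragments counted relative to transcript length and library size, with a row for each of 46947 transcripts and a column for each library. Per the submitters' processing notes, HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 were used. The same notes give the genome build as mm8, a mouse build, whereas the table carries RAP identifiers and chromosomes of rice; the rice assembly and the use of strand are not given in the sources used here. Coordinates are printed as the table gives them. Gene names and descriptions also come from the table, and a gene without a name is printed by its identifier. Annotated lengths were whole multiples of 3 for 93.8% of protein-coding rows, so they are coding lengths. A further 2103 rows are unannotated loci.

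Each FPKM value times its coding length was a whole multiple of what 1 fragment is worth in its library, for 100% of the values above 0 at a tolerance of 0.01. This gave the fragments counted per library, called reads below. The library size implied by the FPKM values differed from the sum of those reads, by a factor from 0.674 in WT control replicate 1 to 1.21 in WT no Pi replicate 2, so the deposited scale is not proportional to the reads counted. Genes with several annotated transcripts were more often listed at 0 in every library: 20.3% of 34488 genes with 1 transcript, 34.3% of 4307 genes with 2 and 39.1% of 1172 genes with 3 or more. SPX1, GLK1, PHR4 and the glutamine synthetase gene GS1;1 are among those listed at 0, and no absence of expression is read from such a value.

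FPKM was summed over the transcripts of each gene, giving 39967 genes, of which 22648 with an FPKM of at least 1 in at least 3 of the 12 libraries were kept. These include 1651 unannotated loci and 2938 genes with more than 1 transcript. The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and a model of 4 group means over all 12 libraries. The fit had 8 residual degrees of freedom and 3.78 prior degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept, in each of 5 comparisons: the response to Pi withdrawal in WT and in phr2, phr2 against WT in control and in no Pi medium, and the difference of the responses (the interaction). Labels were read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

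Gene lists, 18 in number, were fixed as word patterns before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. The patterns were matched at the start of a word in the gene name, the RAP description and the Swiss-Prot name. This choice of fields was settled on the annotation, before any list test was seen. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and beside fry, which asks whether a list's genes move one way on balance. Across the 5 comparisons this made 90 list tests. The named genes are PHR2, DGP1, GLK1 and GLK2. They include for each comparison and list the 2 members with the smallest adjusted p, or 3 for the Pi signalling, lipid, chlorophyll and nitrogen lists. They also include for each comparison the 5 largest rises and 5 largest falls among genes that passed, with no overlap of the group ranges, a group mean FPKM of at least 5 and a name or description. Any further gene that is named was chosen after its values were seen. Another 4 lists, on autophagy, on fatty acid breakdown and the glyoxylate cycle, on amino acid breakdown and on the proteasome, were chosen after the WT response had been seen.

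Depth ranged from 10109727 reads in phr2 control replicate 3 to 13122430 reads in WT no Pi replicate 1. The fit was tested on simulated data, with independent normal noise for each gene around its mean, at its residual spread in these libraries. At each size 50 genes were changed among 22648 genes, all with a mean log2(FPKM + 1) above that of an FPKM of 5. Genes in the simulation are not correlated and no library has a state of its own. The shares and false calls below therefore need not hold for these data or for genes with lower values. For the WT response, the share recovered was 0% at a log2 change of 1, 44% at 2, 82% at 3 and 82% at 4. It was 0%, 36%, 66% and 84% for the phr2 response, and 2%, 32%, 58% and 88% for phr2 against WT in control medium. It was 2%, 50%, 70% and 82% in no Pi medium, and 0%, 12%, 44% and 62% for the interaction. False calls numbered 2 of 106, 5 of 98, 7 of 97, 5 of 107 and 5 of 64, in the same order of comparisons.

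The alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, scaling each library to the same sum of FPKM, median-of-ratios scaling, quantile normalization, no variance trend, robust variances, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and a fit to only the groups compared. Added after the data had been seen were limma voom on the recovered reads, library quality weights (computed gene by gene, after the default method had been run, did not converge and had its counts seen), genes with 1 annotated transcript, and a fit without WT control replicate 1 and the library labelled phr2 no Pi replicate 3. Columns of other samples numbered 0.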

Results

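The leaf RNA of 12 rice libraries was compared across genotype and Pi supply, with 3 libraries in each of the groups WT control, WT no Pi, phr2 control and phr2 no Pi. Reads counted per library ranged from 10109727 to 13122430, and genes at an FPKM of at least 1 numbered from 19482 in WT control replicate 1 to 20611 in phr2 control replicate 3. The 10 most abundant genes took from 6.53% of the reads in WT no Pi replicate 3 to 13.5% in WT control replicate 1. The sum of FPKM per library ranged from 1162552 in WT no Pi replicate 3 to 2292700 in WT control replicate 1.

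The first principal component held 28.6% of the variance and parted the genotypes, with the WT libraries between −94.5 and −7.46 and 5 phr2 libraries between 42.5 and 94.9. The library labelled phr2 no Pi replicate 3 lay at −29.1, among the WT libraries. Its mean correlation was 0.871 with the other libraries of its group and 0.904 with the WT libraries. Its nearest library was WT no Pi replicate 2, at a Pearson r of 0.968 across genes. This was the highest r of any pair of libraries, above the highest within a group (0.930, phr2 no Pi replicates 1 and 2). WT no Pi replicate 2 itself had a mean r of 0.871 with the other WT libraries. Its mean r with the phr2 libraries was 0.883, the library labelled phr2 no Pi replicate 3 included.

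**Figure D1:**
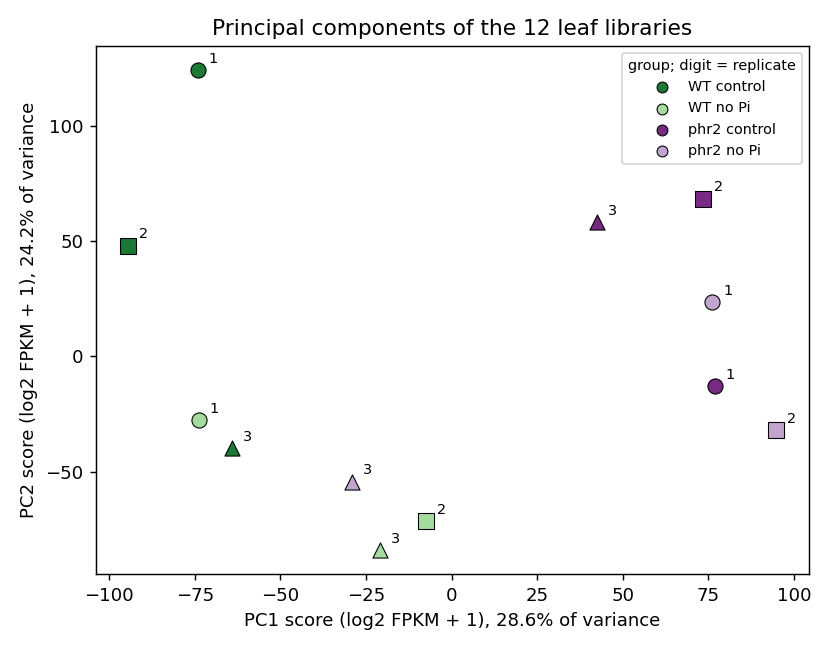
Scores of the 12 libraries on the first and second principal component of log2(FPKM + 1), which hold 28.6% and 24.2% of the variance; each point is a library, its color the group and its digit the replicate. The library labelled phr2 no Pi replicate 3 lies at −29.1 on the first component, among the WT libraries.

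PHR2, the gene named in the mutant's label, was listed at similar levels in all groups. PHR2 (Os07g0438800, chromosome 7, 14753753 to 14759288, plus strand, 2 transcripts) had FPKM values of 27.5, 17.9 and 22.1 in WT control and of 24.8, 31.5 and 24.7 in WT no Pi. The phr2 control libraries gave 29.6, 26.1 and 21.4, and the phr2 no Pi libraries 23.2, 24.2 and 29.7. Its log2 difference between phr2 and WT was 0.19 (SE 0.28, limma adjusted p = 0.741) in control medium and −0.07 (adjusted p = 0.970) without Pi. A mutation that leaves the transcript in place would not show in these values, so PHR2 does not check the genotype labels.

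DGP1, the other gene in the series' title, and GLK2 did not pass in any comparison. DGP1 (DEEP GREEN PANICLE 1, Os01g0837600, chromosome 1, 35912084 to 35913241) averaged 4960 ± 7779 FPKM in WT control and 559 ± 327 in WT no Pi (SD, n = 3). It averaged 247 ± 96.1 in phr2 control and 352 ± 285 in phr2 no Pi. The WT control mean rests on replicate 1, at 13943 FPKM, beside 464 and 473 in the other WT control libraries. The phr2 control libraries all lay lower, at 170, 216 and 354 FPKM. Without Pi the WT libraries gave 931, 317 and 429 FPKM and phr2 replicates 1 and 2 gave 133 and 248. The library labelled phr2 no Pi replicate 3 gave 675. Its log2 change was −1.53 (SE 1.10, adjusted p = 0.410) in the WT response and 0.26 (adjusted p = 0.998) in the phr2 response. The difference between phr2 and WT was −2.62 (adjusted p = 0.235) in control medium and −0.84 (adjusted p = 0.870) without Pi. GLK2, a transcription factor that activates photosynthesis genes (Os01g0239000, chromosome 1, 7686901 to 7693984, minus strand), averaged 121 ± 112, 96.4 ± 38.4, 51.9 ± 13.6 and 68.2 ± 21.3 FPKM in the same order of groups. Its log2 difference between the genotypes was −0.83 in control medium (adjusted p = 0.452) and −0.45 without Pi (adjusted p = 0.865). GLK1 (Os06g0348800) is listed at 0 in every library.

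**Figure D2:**
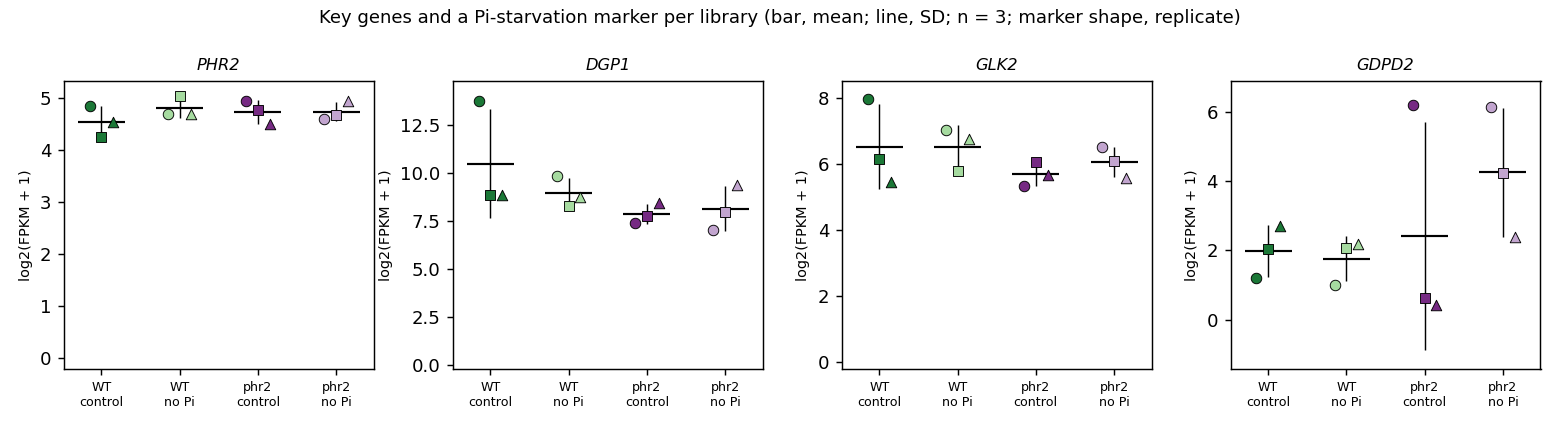
PHR2, DGP1, GLK2 and the Pi-starvation marker GDPD2 per library as log2(FPKM + 1), with points for libraries (shape gives the replicate), bars for group means and lines for the SD (n = 3). PHR2 lies between 17.9 and 31.5 FPKM in all libraries, and DGP1 stands at 13943 FPKM in WT control replicate 1.

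The first comparison asked which leaf genes change in WT after 3 days without Pi. ISOCITRATE LYASE, MALATE SYNTHASE and CHLOROPLAST VESICULATION were among the largest rises, and the lists for light harvesting, chlorophyll synthesis, the Calvin cycle and cytosolic ribosomal proteins fell at camera's preset correlation. None of these 4 list calls held with an estimated correlation (adjusted p = 0.550, 0.624, 0.299 and 0.624), and the Calvin cycle median turned when each library was rescaled to the same FPKM sum. ISOCITRATE LYASE (Os07g0529000), an enzyme of the glyoxylate cycle, rose from 0.709 ± 1.07 to 424 ± 605 FPKM (SD, n = 3; log2 change 6.89, SE 1.11, adjusted p = 0.0301). MALATE SYNTHASE (Os04g0486950), the other enzyme specific to that cycle, rose from 5.88 ± 5.40 to 572 ± 527 FPKM (log2 change 6.15, SE 0.77, adjusted p = 0.0174). CHLOROPLAST VESICULATION (Os05g0575000), which drives vesicles carrying chloroplast proteins to the vacuole, rose from 1.77 ± 0.513 to 258 ± 372 FPKM (log2 change 5.28, adjusted p = 0.0442). YELLOW-GREEN LEAF 18 (Os06g0132400), described as the magnesium-protoporphyrin methyltransferase of chlorophyll synthesis, fell from 1670 ± 649 to 200.3 ± 141 FPKM (log2 change −3.21, SE 0.49, adjusted p = 0.0291). In all, 534 of 22648 genes passed, 217 higher and 317 lower, each by at least 1.11 on the log2 scale. Rescaling to the same FPKM sum turned this balance, with 872 higher and 145 lower.

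The other large rises were a chymotrypsin protease inhibitor (Os01g0615100, log2 change 6.85, adjusted p = 0.0455) and Os01g0266800, described as a lysosomal amino acid transporter (5.15, adjusted p = 0.0174). The largest falls were Os12g0493900, described as a Pumilio-type RNA-binding protein (−5.28, adjusted p = 0.0341), and the phospholipase A2 gene Os03g0261100 (−3.92, adjusted p = 0.0479). They were followed by the RADIALIS-like gene Os05g0579600 (−3.56, adjusted p = 0.0442) and Os05g0226300, described as similar to FIP1 (−3.28, adjusted p = 0.0301).

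**Figure D3:**
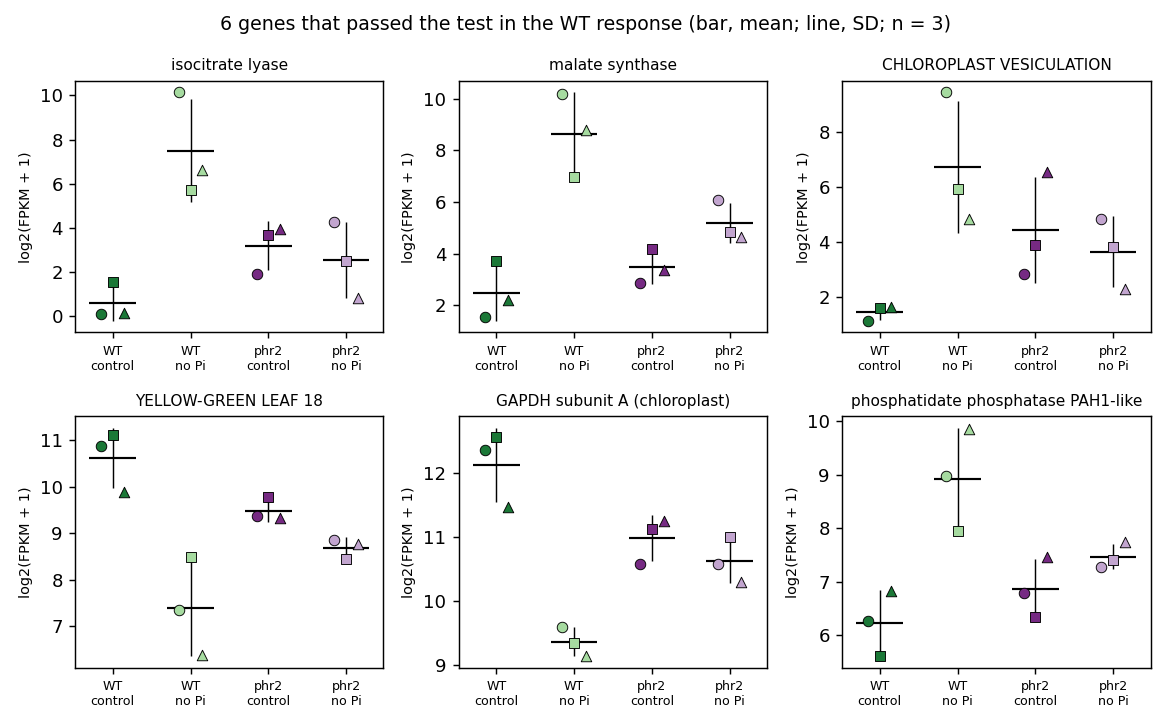
Isocitrate lyase, malate synthase, CHLOROPLAST VESICULATION, YELLOW-GREEN LEAF 18, chloroplast GAPDH subunit A and a PAH1-like phosphatidate phosphatase per library as log2(FPKM + 1), with points for libraries (shape gives the replicate), bars for group means and lines for the SD (n = 3). All 6 passed the test in the WT response. In the phr2 response and in the interaction 0 of all 22648 genes passed, so no difference by genotype is shown for these 6.

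Among photosynthesis genes, the light harvesting and photosystem list fell as a set, with 43 of 50 members below 0 and a median log2 change of −0.95 (camera adjusted p = 9.9e-08, and adjusted p = 0.550 with an estimated correlation). Of its members 2 rose, 6 fell and 42 did not pass, and 3 rose and 23 fell when adjusted over the list alone. The photosystem I chlorophyll-binding protein Os09g0439500 fell from 537 ± 202 to 78.1 ± 48.5 FPKM (log2 change −2.88, adjusted p = 0.0301). PsbS (Os01g0869800), which dissipates excess light energy, fell by 2.44 on the log2 scale (adjusted p = 0.0332). A photosystem II 10 kDa protein gene, Os07g0147550, rose from 0.649 ± 0.304 to 47.8 ± 32.9 FPKM (log2 change 4.64, SE 0.51, adjusted p = 0.0133). The chlorophyll synthesis list had 0 rises, 4 falls and 32 members that did not pass (1 and 8 adjusted over the list alone). Its median was −0.56 (adjusted p = 0.0346, and adjusted p = 0.624 with an estimated correlation). Beside YELLOW-GREEN LEAF 18, ETIOLATED LEAF AND LETHAL (Os03g0563300), a magnesium chelatase subunit, fell from 667 ± 153 to 228 ± 31.3 FPKM (adjusted p = 0.0341), as did DIVINYL REDUCTASE (Os03g0351200, log2 change −1.91, adjusted p = 0.0440). So did the protochlorophyllide reductase FADED GREEN LEAF (Os10g0496900, log2 change −2.18, adjusted p = 0.0442). Quantile normalization ended both set calls, with a median of −0.33 (adjusted p = 0.0878) for light harvesting and −0.25 (0.129) for chlorophyll synthesis. After rescaling, which put the median of all genes at 0.37, their medians were −0.40 and −0.07. Chlorophyll synthesis also missed the threshold with 1-transcript genes (adjusted p = 0.436), with a pseudocount of 0.1 (0.0518) and without WT control replicate 2 (adjusted p = 0.0526), WT control replicate 3 (0.312) or WT no Pi replicate 1 (0.159).

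In carbon metabolism, the Calvin cycle list had a median log2 change of −0.30 (camera adjusted p = 0.00727, and adjusted p = 0.299 with an estimated correlation), which turned to 0.20 after rescaling, below the median of all genes (0.37) there. The call ended with 1-transcript genes (adjusted p = 0.503), under quantile normalization (median −0.17, adjusted p = 0.187) and without WT control replicate 3 (0.108). Of its 45 members 1 rose, 6 fell and 38 did not pass (2 and 12 adjusted over the list alone). Chloroplast GAPDH subunit A (Os04g0459500) fell from 4686 ± 1657 to 662 ± 105 FPKM (log2 change −2.76, SE 0.37, adjusted p = 0.0220). PHOSPHOGLYCERATE KINASE 3 (Os05g0496200) fell from 346 ± 37.2 to 85.8 ± 25.9 (−2.04, adjusted p = 0.0222). The member that rose, Os06g0258900, is described by its Swiss-Prot match as an L-threonate dehydrogenase, which is not an enzyme of the cycle. The sucrose and starch list (1 rose, 3 fell, 96 did not pass; 2 and 6 adjusted over the list alone) did not pass as a set (median −0.24, adjusted p = 0.289). Within it the small subunit of ADP-glucose pyrophosphorylase (Os08g0345800), the gateway to starch, fell from 37.6 ± 12.6 to 7.91 ± 2.80 FPKM (adjusted p = 0.0332). TREHALOSE-6-PHOSPHATE SYNTHASE 11 (Os09g0376800) rose from 2.72 ± 2.23 to 15.9 ± 4.87 (adjusted p = 0.0341). The organic acid and Pi-sparing glycolysis list (0 rose, 3 fell, 38 did not pass; 1 and 7 adjusted over the list alone) had a median of −0.15 (adjusted p = 0.274, and 0.0444 without WT control replicate 1). PHOSPHOENOLPYRUVATE CARBOXYLASE 4 (Os01g0208700) fell from 424 ± 184 to 85.6 ± 50.2 FPKM (adjusted p = 0.0406) and malate dehydrogenase Os05g0574400 fell by 1.69 on the log2 scale (adjusted p = 0.0428).

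None of the classical Pi-starvation lists passed as a set in the WT response. Of 21 Pi signalling genes 0 passed (2 rose and 1 fell adjusted over the list alone; median −0.15, adjusted p = 0.848). PHO1;1 (Os01g0110100) stood at 4.64 ± 1.59 and 1.22 ± 0.491 FPKM (adjusted p = 0.0778) and PHR3 (Os02g0139000) at 12.1 ± 4.57 and 39.1 ± 21.1 FPKM (adjusted p = 0.0803). Among 23 Pi transporter genes 0 rose, 1 fell and 22 did not pass (1 and 1 adjusted over the list alone; median 0.13, adjusted p = 0.568). The fall was in a mitochondrial phosphate carrier, Os03g0263400, from 41.0 ± 14.5 to 11.1 ± 1.52 FPKM (adjusted p = 0.0442). NLA1 (Os07g0673200), a ubiquitin ligase of Pi transporters, stood at 10.6 ± 2.76 and 66.3 ± 48.5 FPKM (adjusted p = 0.0516). In the list of acid phosphatases and S-like RNases 0 rose, 1 fell and 35 did not pass (1 and 3 adjusted over the list alone). Its median was −0.03, while its mean was 0.02 and its test pointed up (adjusted p = 0.971). PURPLE ACID PHOSPHATASE 10D (Os12g0637200) fell from 31.1 ± 19.6 to 3.77 ± 1.57 FPKM (adjusted p = 0.0442). Of 45 membrane lipid remodelling genes 2 rose, 1 fell and 42 did not pass (4 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.626). A phosphatidate phosphatase of the PAH1 type, Os05g0462301, rose from 79.0 ± 32.8 to 554 ± 341 FPKM (log2 change 2.68, adjusted p = 0.0332), and PHOSPHOLIPASE D ALPHA 5 (Os06g0604300) fell by 1.95 on the log2 scale (adjusted p = 0.0332). The other rise, FLOURY ENDOSPERM 19 (Os04g0119400, 2.31, adjusted p = 0.0428), is a pyruvate dehydrogenase subunit and not an enzyme of membrane lipids.

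Cytosolic ribosomal protein genes fell as a set, with 180 of 217 members below 0 and a median log2 change of −0.82 (camera adjusted p = 4.1e-12, and adjusted p = 0.624 with an estimated correlation). The median shrank to −0.33 under quantile normalization (adjusted p = 0.00258) and to −0.28 after rescaling, against 0.37 for all genes there. The sums of FPKM run the same way, from 1410691 to 2292700 in WT control and from 1162552 to 1457875 in WT no Pi. Of these genes 0 rose, 3 fell and 214 did not pass, and 1 rose and 58 fell adjusted over the list alone. The 40S protein gene Os03g0249400 fell from 215 ± 60.8 to 50.7 ± 24.8 FPKM (adjusted p = 0.0332) and Os01g0100700 from 504 ± 238 to 125 ± 38.1 (adjusted p = 0.0442). In the senescence and chlorophyll breakdown list 1 rose, 0 fell and 29 did not pass (4 and 1 adjusted over the list alone; median 0.24, adjusted p = 0.274). SULFURTRANSFERASE 9 (Os06g0725000), similar to the dark-induced protein DIN1, rose from 5.89 ± 0.888 to 152 ± 125 FPKM (log2 change 3.99, adjusted p = 0.0350). NON-YELLOW COLORING 3 (Os06g0354700), a chlorophyll breakdown gene, stood at 1.62 ± 1.01 and 12.7 ± 3.57 FPKM (adjusted p = 0.0501).

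The nitrogen uptake and assimilation list had 0 rises, 1 fall and 122 members that did not pass (0 and 0 adjusted over the list alone; median −0.26, adjusted p = 0.289). The fall was in the NRT1/PTR transporter gene Os05g0410900, from 34.8 ± 14.99 to 8.04 ± 1.60 FPKM (adjusted p = 0.0488). The nitrate reductase gene Os01g0693700 stood at 13.4 ± 5.31 and 3.22 ± 1.23 FPKM (adjusted p = 0.0521). The circadian clock list (22 genes, none passed, 0 and 0 adjusted over the list alone) had a median of 0.45 (adjusted p = 0.289). CCA1 (Os08g0157600), a morning clock factor, stood at 10.8 ± 6.06 and 52.0 ± 37.3 FPKM (adjusted p = 0.111). For iron and metal homeostasis 1 of 46 rose, an NRAMP metal transporter gene (Os01g0503400, log2 change 3.56, adjusted p = 0.0350), with 1 and 0 adjusted over the list alone (median 0.11, adjusted p = 0.820). In the jasmonate and defence list 1 of 211 rose, the class III chitinase-like gene Os05g0247100 (2.99, adjusted p = 0.0442), and 1 fell, WRKY68 (Os04g0605100, −1.80, adjusted p = 0.0442). Adjusted over the list alone, 0 and 0 passed (median −0.16, adjusted p = 0.820). Heat shock and protein folding genes included 2 rises, 2 falls and 174 that did not pass (2 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.289). Among them the small heat shock protein gene Os02g0128000 fell from 26.03 ± 13.4 to 3.14 ± 2.46 FPKM (adjusted p = 0.0442). Of 77 DNA replication and cell division genes, 1 fell, a histone H2B gene (Os09g0570850, −2.34, adjusted p = 0.0332), with 0 and 1 adjusted over the list alone (median −0.07, adjusted p = 0.848). No gene of the 12 root and endodermis markers passed (0 and 2 adjusted over the list alone; median −0.57, adjusted p = 0.289). CASPARIAN STRIP protein 2 (Os08g0101900) stood at 25.8 ± 16.4 and 5.44 ± 5.96 FPKM (adjusted p = 0.0746).

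The count of 534 rests on single libraries and on the groups in the fit, being 0 in a fit to the WT groups alone. It was 0 without WT control replicate 2 or WT no Pi replicate 1, 1 without WT control replicate 1 or WT no Pi replicate 3. It was 157, 80 and 160 without phr2 control replicates 1, 2 and 3, 67 and 18 without phr2 no Pi replicates 1 and 2, and it was 3155 without WT control replicate 3, which kept all 534. With WT control replicate 1 and the library labelled phr2 no Pi replicate 3 both left out, a choice made after seeing the data, it was 114, and voom called 107. The group ranges did not overlap for 5619 genes, 24.8% of those tested, where chance gives 10% on average. Genes are not independent, so the share in a single chance split can lie far from 10%. Its spread between splits was not computed, so this share does not exclude chance. In limma 5671 genes had an unadjusted p under 0.05.

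**Figure D4:**
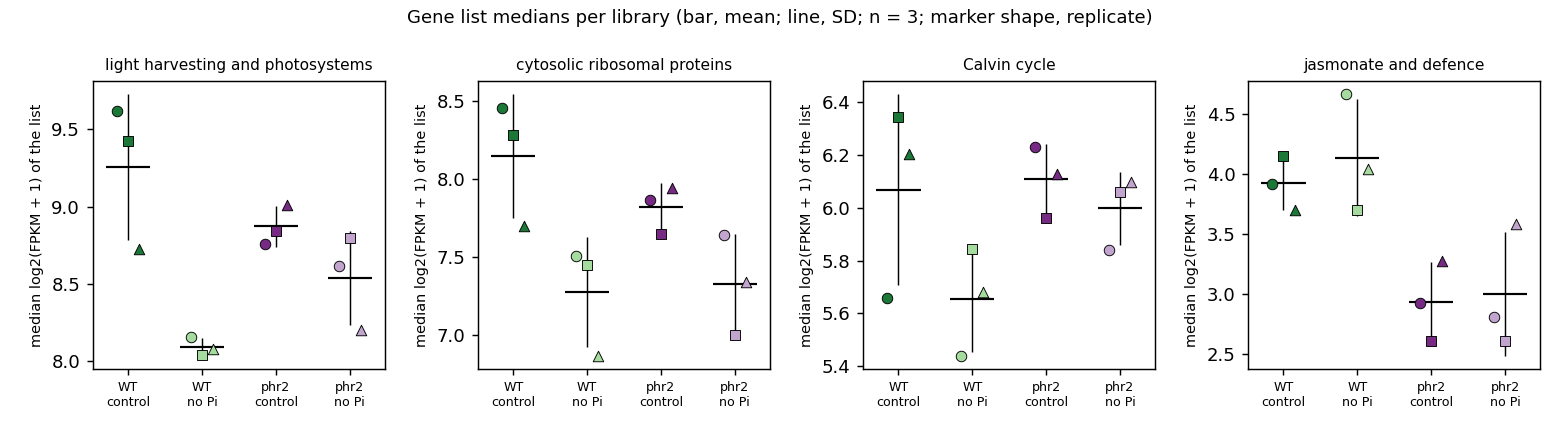
Median log2(FPKM + 1) of the light harvesting, cytosolic ribosomal, Calvin cycle and jasmonate lists per library, with points for libraries (shape gives the replicate), bars for group means and lines for the SD (n = 3). The WT response has a median change of −0.95 in the light harvesting list, −0.82 in the ribosomal list and −0.30 in the Calvin cycle list, the last turning to 0.20 after rescaling to the same FPKM sum.

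The same response in the phr2 mutant was measured to ask what remains of it in the mutant. No gene passed in limma. At an unadjusted p under 0.05 there were 885 genes (3.91%), a share below the 0.05 expected without any change. Voom also called 0 (854 unadjusted). The limma count of genes that passed was 33 without phr2 control replicate 1 and 3 without WT control replicate 1. Cytosolic ribosomal protein genes fell as a set here too, with 199 of 217 members below 0 and a median log2 change of −0.51 (camera adjusted p = 3.1e-19, and adjusted p = 0.570 with an estimated correlation), though no member passed alone. The photosystem II 10 kDa gene Os07g0147550 stood at 1.64 ± 0.473 FPKM in phr2 control and 14.9 ± 4.49 in phr2 no Pi (log2 change 2.56, adjusted p = 0.973). Its neighbor Os07g0147500, with the same description, stood at 70.9 ± 19.1 and 3577 ± 719 (5.66, SE 1.84, adjusted p = 0.998). The SE is pooled over all 4 groups, WT included, so this p does not measure the spread within the phr2 groups alone. A limma fit to the phr2 groups alone called 1 gene, higher without Pi and not identified here (smallest adjusted p = 0.00569).

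Other named genes of the phr2 response, none of which passed, include pyruvate phosphate dikinase 2 (Os03g0432100), at 2.40 ± 2.05 and 27.7 ± 10.01 FPKM, and CHITINASE 4 (Os04g0493400) at 190.1 ± 144 and 7.56 ± 6.81 FPKM. The sugar transporter gene SWEET2A (Os01g0541800) stood at 6.91 ± 1.87 and 41.7 ± 32.0 FPKM. YELLOW-GREEN LEAF 18 had a log2 change of −0.80 (SE 0.49, adjusted p = 0.998). The light harvesting list had a median of −0.25 (adjusted p = 0.0571, 1 and 0 adjusted over the list alone), the Calvin cycle list −0.31 (adjusted p = 0.131) and the lipid list 0.20 (adjusted p = 0.195). Light harvesting passed without phr2 control replicate 1 (adjusted p = 0.0160), phr2 no Pi replicate 2 (9.7e-06) or WT control replicates 2 (0.0496) or 3 (0.0414). Calvin cycle genes passed without phr2 no Pi replicate 2 (0.00855), and both they and the lipid list did without phr2 control replicate 3 (0.0481). Medians were −0.21 for the iron list (adjusted p = 0.197), −0.23 for the clock list (adjusted p = 0.226) and 0.05 for the organic acid list (adjusted p = 0.900, 1 and 0 adjusted over the list alone). No member of the remaining lists passed over all genes or over its list alone, and none of those lists passed as a set. Signs differed for Pi signalling (median −0.04, mean 0.00, test downward), Pi transporters (median −0.03, mean 0.02, test downward) and root markers (median 0.00, mean −0.05, test upward). GDPD2 (Os02g0514500), a phosphodiesterase of Pi-starved membranes, varied between libraries of a group, at 24.7 ± 42.1 and 30.6 ± 34.5 FPKM. Group ranges did not overlap for 2208 genes, 9.75% against 10% by chance on average.

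To set the genotypes apart with Pi present, phr2 control was compared with WT control. A sugar transporter gene and 2 bHLH genes were among the largest falls in phr2, and the jasmonate and defence list was lower at camera's preset correlation (adjusted p = 7.8e-06) but not with an estimated one (0.937). MONOSACCHARIDE TRANSPORTER 6 (Os07g0559700), a hexose importer, fell from 4057 ± 2041 FPKM in WT control to 61.2 ± 13.5 in phr2 control (SD, n = 3; log2 change −5.90, SE 1.08, adjusted p = 0.0433). The transcription factor gene bHLH148 (Os03g0741100) fell from 2072 ± 1132 to 32.9 ± 18.4 FPKM (−5.93, SE 1.04, adjusted p = 0.0428). A related gene, bHLH185 (Os01g0773800), fell from 333 ± 162 to 0.0644 ± 0.0573 FPKM (−8.17, SE 1.55, adjusted p = 0.0467). Of 151 genes that passed, 18 were higher and 133 lower in phr2.

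The further large falls were the U-box protein gene Os02g0540700 (−6.18, adjusted p = 0.0486) and the MATE-type transporter gene Os04g0571600 (−5.99, adjusted p = 0.0467). Rises included CALCINEURIN B-LIKE PROTEIN 9 (Os01g0579600), a calcium sensor, from 3.61 ± 0.673 to 26.5 ± 5.51 FPKM (2.57, SE 0.34, adjusted p = 0.0421), and the cytochrome P450 gene 71Z2 (Os07g0217600, 3.10, adjusted p = 0.0491). The others were Os05g0509500, described as a signal recognition particle protein (2.93, adjusted p = 0.0494), the dormancy- and auxin-associated gene Os09g0437500 (2.42, adjusted p = 0.0458) and the zinc finger gene Os10g0142100 (2.35, adjusted p = 0.0428).

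The jasmonate and defence list fell as a set, with 144 of 211 members below 0 and a median of −0.75 (camera adjusted p = 7.8e-06, and adjusted p = 0.937 with an estimated correlation). The median was −0.62 under quantile normalization and −0.39 after rescaling, where the medians of all genes were 0.15 and 0.30. In it 0 rose, 9 fell and 202 did not pass, and 4 rose and 47 fell adjusted over the list alone. ALLENE OXIDE SYNTHASE 1 (Os03g0767000), an enzyme of jasmonate synthesis chosen after its values were seen, was lower by 4.49 on the log2 scale, given here without a test result. The chitinase gene Os01g0860500 fell from 605 ± 247 to 14.8 ± 8.77 FPKM (adjusted p = 0.0428) and the thionin-like gene Os07g0432333 from 46.8 ± 18.4 FPKM to values listed at 0 (adjusted p = 0.0428). The organic acid list had 0 rises and 2 falls (0 and 5 adjusted over the list alone; median 0.21, mean −0.08, test downward, adjusted p = 0.882), both in pyrophosphate-dependent phosphofructokinase genes. Os01g0191700 fell from 299.9 ± 74.0 to 70.1 ± 7.08 FPKM (adjusted p = 0.0428) and Os05g0194900 fell by 2.36 on the log2 scale (adjusted p = 0.0486). In the sucrose and starch list TREHALOSE-6-PHOSPHATE SYNTHASE 5 (Os02g0790500) fell from 1287 ± 459 to 218 ± 63.2 FPKM (adjusted p = 0.0491; 1 and 5 adjusted over the list alone; set adjusted p = 0.366). The single fall in the chlorophyll list (0 and 1 adjusted over the list alone; set adjusted p = 0.844) was Os01g0631200, which makes siroheme, not chlorophyll (478 ± 347 to 58.9 ± 29.3 FPKM, adjusted p = 0.0491).

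No member of the other 14 lists passed over all genes, and none of those lists passed as a set. Adjusted over the list alone, 2 and 3 acid phosphatases rose and fell, as did 0 and 1 of the lipid list, 0 and 2 of the Calvin cycle list and 0 and 2 of the senescence list. Medians and means differed in sign, with the test on the side of the median, for Pi signalling (0.19 and −0.02), Pi transporters (0.10 and −0.03), acid phosphatases (0.00 and −0.04), light harvesting (−0.05 and 0.00) and root markers (−0.09 and 0.05). The test took the side of the mean for lipid remodelling (0.06 and −0.30) and senescence (0.16 and −0.13). The ribosomal list had a median of −0.26 (adjusted p = 0.267, and 1.4e-04 without WT control replicate 3), which quantile normalization turned to 0.26 (adjusted p = 0.0421). The light harvesting list had −0.05 (adjusted p = 0.979), turned to 0.33 (0.177). The DNA replication list passed without WT control replicate 1 (0.0376).

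Voom called 0 genes in this comparison, with 3869 at an unadjusted p under 0.05, beside 4189 in limma. The count of 151 became 586 without WT control replicate 1 and 0 without WT control replicate 2 or phr2 control replicates 2 or 3. It was 4 without WT control replicate 3, 75, 20 and 6 without WT no Pi replicates 1, 2 and 3, 98 without phr2 no Pi replicate 2 and it was 770 without the library labelled phr2 no Pi replicate 3, which kept all 151. With WT control replicate 1 and the library labelled phr2 no Pi replicate 3 both left out it was 1178. Group ranges did not overlap for 4755 genes, 21.0% against 10% by chance on average. The spread of this share between splits was not computed, so it does not exclude chance.

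The genotypes were also compared in the medium without Pi. No gene passed in limma (1963 at an unadjusted p under 0.05) or in voom (1966 unadjusted), and the smallest adjusted p was 0.541. Light harvesting and photosystem genes were higher in phr2 as a set, with 44 of 50 members above 0 and a median log2 difference of 0.82, or 0.52 under quantile normalization (camera adjusted p = 7.4e-10, and adjusted p = 0.233 with an estimated correlation). Jasmonate and defence genes were lower as a set, with 164 of 211 members below 0 and a median of −0.81 (camera adjusted p = 3.4e-10, and adjusted p = 0.233 with an estimated correlation). The jasmonate repressor genes TIFY 11E (Os10g0391400) and TIFY 11A (Os03g0180800) stood at 269 ± 314 and 175 ± 198 FPKM in WT no Pi and at 20.1 ± 33.9 and 17.2 ± 29.5 in phr2 no Pi. In the library labelled phr2 no Pi replicate 3 TIFY 11E (Os10g0391400) stood at 59.2 FPKM, beside 0.324 and 0.679 in the other phr2 no Pi libraries.

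The Calvin cycle list (median 0.24, 33 of 45 members above 0) had a camera adjusted p of 0.0356, and adjusted p = 0.233 with an estimated correlation. For the organic acid list (median 0.22, 26 of 41 above 0, 1 and 0 adjusted over the list alone) the camera adjusted p was 0.0362, and adjusted p = 0.347 with an estimated correlation. GAPDH subunit A stood at 662 ± 105 FPKM in WT no Pi and 1609 ± 394 in phr2 no Pi (log2 difference 1.26, adjusted p = 0.541). The phosphoenolpyruvate carboxylase kinase gene Os04g0517500 stood at 1.02 ± 1.04 and 13.3 ± 10.8 FPKM, and SULFURTRANSFERASE 9 at 152 ± 125 and 13.0 ± 11.1 FPKM (−3.26, adjusted p = 0.541). The chlorophyll list (median 0.23, adjusted p = 0.0566) and the senescence list (median −0.34, adjusted p = 0.0602, 0 and 1 adjusted over the list alone) did not pass, nor did the other 12. Quantile normalization brought both past the threshold (0.0446) and also the ribosomal list, from a median of 0.02 to 0.21 (adjusted p = 0.00794). The chlorophyll list also passed without WT no Pi replicate 3 (0.0488) or phr2 no Pi replicate 1 (0.0102), and with a mean FPKM of at least 5 (0.0125). The senescence (0.0261) and ribosomal (0.00187) lists passed without phr2 no Pi replicate 2. In 2 of the other lists the signs differed, the DNA replication list with a median of −0.03 and a test upward, and the sucrose and starch list with a median of 0.04, a test upward and a mean of −0.02. Group ranges did not overlap for 2586 genes, 11.4% against 10% by chance on average.

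Of the no Pi libraries, the one labelled phr2 no Pi replicate 3 lay with WT: without it 269 genes passed, without it and WT control replicate 1 641 passed, and 51 passed without WT no Pi replicate 2. The Calvin cycle call ended without WT no Pi replicate 2 (adjusted p = 0.0548), phr2 no Pi replicate 2 (0.0908) or the library labelled phr2 no Pi replicate 3 (0.0978), without the latter and WT control replicate 1 (0.101) and with 1-transcript genes (0.327). The organic acid call ended without WT no Pi replicate 2 (0.206) or phr2 no Pi replicate 1 (0.101) and with 1-transcript genes (0.0597); its median was 0.40 under quantile normalization.

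The interaction asked whether the response to Pi withdrawal differs by genotype. No gene passed in limma (2002 at an unadjusted p under 0.05) or in voom (1898 unadjusted), and the smallest adjusted p was 0.422. The light harvesting and photosystem list was the 1 list past the threshold, its response less negative in phr2 in 38 of 50 members, with a median difference of 0.82 (camera adjusted p = 1.2e-04, and adjusted p = 0.494 with an estimated correlation). Quantile normalization ended the call, at a median of 0.15 (adjusted p = 0.184), and rescaling gave 0.41, against −0.30 for all genes. PsbS (Os01g0869800) stood at 7678 ± 4102 and 1276 ± 225 FPKM in WT control and no Pi, and at 3748 ± 664 and 2718 ± 577 in phr2. For GAPDH subunit A the difference of responses was 2.40 (SE 0.52, adjusted p = 0.422), for PHOSPHOGLYCERATE KINASE 3 it was 2.11 (SE 0.40, adjusted p = 0.422) and for YELLOW-GREEN LEAF 18 it was 2.42 (SE 0.69, adjusted p = 0.485). PHOSPHOLIPASE D ALPHA 5 had a difference of 2.72 (SE 0.49, adjusted p = 0.422).

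The chlorophyll (median 0.45), Calvin cycle (0.25), organic acid (0.23), ribosomal (0.32), clock (−0.63) and heat shock (−0.17) lists each had an adjusted p of 0.0729 for the interaction. Adjusted over the list alone, 2 Calvin cycle genes and 1 lipid gene passed, all with a positive difference. The Pi signalling list had a median of −0.24 beside a mean of 0.03 and an upward test, and the acid phosphatase list a median of −0.05 beside a mean of 0.04 and an upward test. These and the other lists did not pass. Without WT control replicate 1 the chlorophyll (adjusted p = 0.0158), Calvin cycle (0.0269), organic acid, clock, sucrose and starch, and DNA replication lists (0.0251 each) passed. The ribosomal list passed without any 1 of WT control replicate 3 (1.3e-04), WT no Pi replicates 1 (0.0268) and 2 (0.0371), phr2 control replicate 3 (0.0152) and phr2 no Pi replicate 2 (0.00306). Without phr2 control replicate 1 the clock and heat shock lists passed (0.0363). Without phr2 no Pi replicate 1 the chlorophyll, Calvin cycle and clock lists passed (0.0459), and the organic acid list did without the library labelled phr2 no Pi replicate 3 (0.0400). Without WT no Pi replicate 2 the count of genes was 5, and without phr2 control replicate 1 it was 26.

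Across all 22648 genes, which are not independent replicates, the WT and phr2 log2 changes correlated with a Pearson r of 0.251 and a Spearman rho of 0.294. Of the 534 genes that passed in WT, 428 (80.1%) had the same sign in phr2. Their median change was 2.11 in WT and 0.25 in phr2 among those that rose, and −2.03 and −0.48 among those that fell. Since genes picked in WT have inflated WT changes, the medians were also taken in 1 library of each WT group left out of the choice. With replicate 3 left out, 92 genes rose and 133 fell, with medians of 1.44 and −1.68 in the libraries left out and of 0.38 and −0.58 in phr2. With replicate 2 left out, 31 rose and 14 fell, with medians of 1.55 and −1.88 in the libraries left out and of 0.37 and −0.72 in phr2, while no gene passed with replicate 1 left out. On an axis from the WT control mean at 0 to the WT no Pi mean at 1, phr2 control lay at 0.385 ± 0.0580 and phr2 no Pi at 0.563 ± 0.0309 (SD, n = 3). WT libraries left out of the choice of genes in turn lay at 0.0804 to 0.531 for control and at 0.440 to 0.782 for no Pi, so the ends at 0 and 1 are inflated by that choice. The phr2 groups did not overlap, and the exact permutation p of 0.1, two-sided, is the smallest this design can give. The axis genes were ranked with a variance taken over all 12 libraries, which prefers genes with a small spread within the phr2 groups. The phr2 SDs, the lack of overlap and this p are therefore not free of the phr2 labels. With genes chosen from WT libraries alone, 1 left out in turn, the library labelled phr2 no Pi replicate 3 lay at 0.287 to 0.787.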

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

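The tests of a wrong genotype label, a swap, a mixture, low depth, lost reads and too few marker reads, and the splits for the interaction, were chosen after the result had been seen, the others before. The light harvesting and photosystem list stands out because the test of the difference between the genotypes' responses itself passed at the preset correlation (camera adjusted p = 1.2e-04), though not with an estimated correlation (adjusted p = 0.494). Its median change was −0.95 in WT and −0.25 in phr2, and 38 of 50 members were less negative in phr2, with a median difference of 0.82, or 0.15 under quantile normalization (adjusted p = 0.184). Chance cannot be excluded for the count of lists. The genotype and treatment effects were taken out and the rest regrouped within each treatment, in 100 of the 200 different splits, the real one included. Of these 90 gave at least the real count of 1 list, with 8 the highest other. At an unadjusted p under 0.05, 14 of the 100 splits gave at least the real count of 2002 genes, with 5013 the highest other, so chance cannot be excluded there either. The real count of 0 genes past the threshold decides nothing, since all 100 splits reach it by construction; the highest other was 227. That split puts WT control replicate 1 with phr2 control replicates 2 and 3, and WT no Pi replicate 2 with phr2 no Pi replicate 2 and the library labelled phr2 no Pi replicate 3. It may point to a structure of the samples beside genotype and treatment, which was not tested.

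The library labelled phr2 no Pi replicate 3 lay at 0.0430 on an axis from the WT mean at 0 to the phr2 mean at 1, where the WT libraries spanned −0.0307 to 0.386 and the other phr2 libraries 0.644 to 0.979. A swap with a WT library is argued against by the 0 WT libraries found within the phr2 range. A mixture of comparable parts of both RNAs is argued against by WT shares of 88.0% and 95.4% from 100 genes higher in WT and 100 higher in phr2, 7.44 percentage points apart. A wrong genotype label is consistent with the position of 0.0430 and remains a hypothesis. On an axis from WT control at 0 to WT no Pi at 1 the same library lay at 0.557, between the other phr2 no Pi libraries (0.536 and 0.596), as its label says. WT libraries left out of that axis in turn overlapped, at 0.0804 to 0.531 for control and 0.440 to 0.782 for no Pi, so this position does not decide. On those axes, with genes chosen from the remaining WT libraries, the library labelled phr2 no Pi replicate 3 itself moved between 0.287 and 0.787. A jasmonate and stress state of a true phr2 sample stays open, since without stress-correlated genes (70.6% of genes left) the library lay at −0.0970, outside WT (0.213 to 1.047) and phr2 (0.344 to 1.28) ranges that overlap each other.

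DGP1 stood at 13943 FPKM in WT control replicate 1, which is 14.98 times the next highest library, at 931 FPKM. A few reads at low depth are argued against by its 33886 reads, 0.290% of that library. A general state of that library stays open. DGP1 was at rank 4 of its genes by this ratio, and 9 genes there exceeded every other library more than 8 times, against up to 43 in another library. Yet 114 genes there exceeded every other library more than 4 times, the highest number of the 12 libraries (112 and 96 in the next). A high rank was taken beforehand to exclude such a state, which was wrong, since a state that raises many genes can raise DGP1 among the most. A count over 8 times no higher than in other libraries was also taken beforehand to exclude it, and this was met. The count over 4 times was not part of that prediction and runs the other way, so the counts do not decide. Reads shared with a neighboring gene also stay open, with a largest ratio of 2.89 among 6 kept genes within 20 kb. No biological explanation was tested.

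Pi-starvation markers did not follow the no Pi label in WT, and in phr2 they followed it only in part. Of 12 markers 8 were detected (SPX2, SPX5, SPX-MFS2, IPS1, PAP10a, GDPD2, MGD3 and SQD2.1). Their mean centred log2 level was 1.96, 0.62 and −0.49 in phr2 no Pi replicates 1, 2 and 3. It was 1.84, −0.65 and −0.82 in phr2 control replicates 1, 2 and 3, −0.71 to −0.41 in WT no Pi and −0.51 to −0.03 in WT control. Reads lost between transcripts stay open, since of the 6 detected markers with 1 transcript, whose median change was −0.26 in the WT response, 2 had at least 10 reads in every WT library. A wrong treatment label on phr2 control replicate 1 stays open. Its position was 0.433 between WT control at 0 and WT no Pi at 1, below the phr2 no Pi libraries at 0.536 to 0.596. A position below these was taken beforehand to exclude such a label, which was wrong, since WT libraries left out of the axis overlap between treatments. Too few marker reads stay open, since 3 markers had at least 10 reads in every WT no Pi library. A leaf Pi supply that differed between single plants was not tested. In every WT no Pi library 2 markers were lower and 0 higher than in every WT control library. These were SPX-MFS2 and SPX2, of which SPX2 lay near the floor, with 2 reads in each WT control library and 0, 1 and 0 in WT no Pi.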

How the results depend on the processing

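Voom, the library quality weights, the 1-transcript genes and the fit without WT control replicate 1 and the library labelled phr2 no Pi replicate 3 (the 2 doubted libraries) were chosen after the result had been seen. Counts of genes past the threshold in limma are given below against 534 in the WT response, 0 in the phr2 response and 151 for phr2 against WT in control medium.

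Without a filter on low values, which tests 31017 genes, the counts were 86, 1 and 6. Rescaling each library to the same FPKM sum gave 1017, 1 and 0, with 85.7% of the WT calls higher against 40.6%; it moved the median of all genes by 0.38 in the WT response, 0.28 in the control genotype comparison and −0.32 in the interaction. Quantile normalization gave 241 in the WT response (46.9% higher) and 5 in the control genotype comparison, where it moved that median by 0.13. Voom called 107 and 0 in these comparisons, all 107 among the 534. Quality weights gave 5390, 1 and 2487; they weigh WT control replicate 2 at 2.71 and replicate 1 at 0.429, and the default way of computing them did not converge. A fit to only the groups compared gave 0, 1 and 274, and an adjusted p of 0.01 gave 0 in the WT response and 0 in the control genotype comparison. A pseudocount of 0.1, a mean FPKM of at least 5, median-of-ratios scaling, no variance trend, robust variances and 1-transcript genes kept both counts above 0 within 1.5 times. Median-of-ratios scaling shared 524 of its 525 WT calls with the 534, so the deposited values lie close to that scale and it tests little.

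Without the doubted libraries the counts were 114 in the WT response (52 shared), 1178 in the control genotype comparison (150 shared) and 641 between genotypes without Pi. The correlation of the responses was then 0.183, against 0.251, the median ratio of the responses 0.0791, against 0.193, and the list tests past the threshold 17, against 11. Leaving out each library in turn gave 0 to 3155 genes in the WT response, 0 to 33 in the phr2 response, 0 to 770 and 0 to 269 for the genotype in control and no Pi medium, and 0 to 26 in the interaction. The correlation then ranged from 0.108 to 0.316, the list tests from 10 to 19, and the ratio, given by 10 of these fits, from −0.129 (reversed, from 1 gene, without WT control replicate 1) to 0.489 (also from 1 gene, without WT no Pi replicate 3). Of the list tests 7 passed with 1-transcript genes, 0 with an estimated correlation and 2 in fry. With the replicate block 174 genes passed in the WT response (162 shared) and 0 in the control genotype comparison. The labels do not say whether a replicate number marks a shared plant or day. Of 18 same-number pairs 5 correlated above 0.1, with 3 libraries closest to their own number. The cause was not tested for these changes, except that a stricter p lowers a count by construction.

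Named gene results past the threshold numbered 51, none reversed, and each was kept by 1 to 9 of the 12 fits that leave out a library; 30 stayed past it after rescaling and 23 after quantile normalization. Of 90 list medians 24 changed sign after rescaling (4 relative to the median of all genes), 1 with median-of-ratios scaling and 19 under quantile normalization (13). Quantile normalization brought 4 further lists past the threshold, of which ribosomal proteins in the control genotype comparison reversed (adjusted p = 0.0421). Among list tests, leaving out a library made 31 stronger and 9 weaker. No alternative varied depth; the spread within groups was 20.7 to 78.4 times the counting noise, and a simulated log2 change of 1 was recovered for 0% of genes in the WT response.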

Other observations

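The 4 lists in this part were chosen after the WT response had been seen, and the autophagy word pattern was narrowed after its first result, because it also took in acyl-CoA oxidases. The splits for the interaction were chosen after its result had been seen. The p-values for these lists come from the data that prompted the lists, so they describe the libraries and the pattern is a hypothesis. In WT leaves without Pi, 23 of 26 genes of fatty acid breakdown and the glyoxylate cycle had a log2 change above 0, with a median of 1.22 (camera adjusted p = 1.3e-08, and adjusted p = 0.0273 with an estimated correlation). Of its members 8 rose, 0 fell and 18 did not pass. Without isocitrate lyase and malate synthase the median was 1.11 (adjusted p = 7.5e-07, and adjusted p = 0.0491 with an estimated correlation), and without all 8 it was 0.59 (adjusted p = 0.00236, and adjusted p = 0.0671 with an estimated correlation). Beside isocitrate lyase and malate synthase, the acyl-CoA oxidase genes ACYL-COA OXIDASE 4 (Os05g0163700) rose from 30.4 ± 15.5 to 178 ± 80.4 FPKM (SD, n = 3; adjusted p = 0.0332) and Os11g0605500 from 5.64 ± 3.93 to 43.4 ± 19.7 FPKM (adjusted p = 0.0332). LONG-CHAIN ACYL-COA SYNTHASE 2 (Os11g0147000), which activates fatty acids, rose from 21.5 ± 13.6 to 75.7 ± 5.73 FPKM (adjusted p = 0.0442).

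Of 28 amino acid breakdown genes 19 were above 0, with a median of 0.70 (camera adjusted p = 0.00140, and adjusted p = 0.0244 with an estimated correlation). In this list 2 rose, 0 fell and 26 did not pass, and without the 2 the median was 0.44 (adjusted p = 0.0115, and adjusted p = 0.0671 with an estimated correlation). Both are of the electron transfer flavoprotein path that takes electrons from branched-chain amino acids to the respiratory chain. Its oxidoreductase gene (Os10g0516300) rose from 3.45 ± 2.60 to 32.9 ± 26.4 FPKM (adjusted p = 0.0336) and its alpha subunit gene (Os03g0835400) from 10.2 ± 3.18 to 50.8 ± 26.8 FPKM (adjusted p = 0.0442). Autophagy genes had a median of 0.68 with 27 of 32 above 0 (camera adjusted p = 4.5e-06, and adjusted p = 0.0549 with an estimated correlation), and 1 rose, the ATG2-like gene Os06g0267600, from 9.04 ± 8.27 to 38.9 ± 12.5 FPKM (adjusted p = 0.0495). Proteasome genes had a median of 0.20 (camera adjusted p = 0.0436, and adjusted p = 0.420 with an estimated correlation), 0 of 49 passed alone, and the set call held in 19 of 25 settings. The other 3 lists passed with camera in all 25 settings, with highest adjusted p of 5.2e-07 for fatty acid breakdown, 0.0214 for amino acid breakdown and 7.8e-05 for autophagy. With an estimated correlation fatty acid and amino acid breakdown each passed in 22 settings and autophagy in 3 (highest adjusted p = 0.142), and without the 2 doubted libraries each had adjusted p = 0.0552.

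In the phr2 response none of the 4 lists passed, with medians of 0.22 for fatty acid breakdown (adjusted p = 0.0869), 0.02 for amino acid breakdown (0.435), 0.09 for autophagy (0.435) and −0.09 for the proteasome (0.274). The interaction was negative for fatty acid breakdown (median −1.02, 22 of 26 members below 0, adjusted p = 5.5e-07, and adjusted p = 0.0462 with an estimated correlation) and for amino acid breakdown (−0.49, 18 of 28, 0.00368, and adjusted p = 0.0390 with an estimated correlation). It was also negative for autophagy (−0.60, 28 of 32, 2.2e-05, and adjusted p = 0.0718 with an estimated correlation) and for the proteasome (−0.30, 34 of 49, 0.00397, and adjusted p = 0.259 with an estimated correlation). With an estimated correlation the interaction passed in 9 of 25 settings for fatty acid breakdown, 13 for amino acid breakdown, 1 for autophagy and 0 for the proteasome. Without the 2 doubted libraries that adjusted p was 0.147 for fatty acid breakdown and 0.138 for amino acid breakdown. Without isocitrate lyase and malate synthase it was 0.0718 for fatty acid breakdown. Without the members that passed in WT it was 0.0982 for each of these 2 lists and for autophagy. The directions held in all 25 settings, and with camera at the preset correlation the proteasome call ended without WT no Pi replicate 1, at adjusted p = 0.0732. Between phr2 and WT in control medium, medians were 0.57 for autophagy (adjusted p = 5.0e-05), 0.43 for fatty acid breakdown (0.00622), 0.23 for the proteasome (0.00328) and 0.22 for amino acid breakdown (0.545), and none passed with an estimated correlation (adjusted p = 0.220 for autophagy, 0.295 for fatty acid breakdown and for the proteasome). Without Pi they were −0.52 for fatty acid breakdown (adjusted p = 1.4e-04, and adjusted p = 0.118 with an estimated correlation) and −0.45 for amino acid breakdown (5.8e-04, and adjusted p = 0.0141 with an estimated correlation). Autophagy was at −0.07 (adjusted p = 0.801) and the proteasome at 0.02 (0.915).

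Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. Genes past the threshold numbered 534 in the WT response (highest other split 0), 0 in the phr2 response (19), 151 for phr2 against WT in control medium (29) and 0 without Pi (3). The fixed lists past the threshold numbered 4 (highest other 5), 1 (8), 1 (3) and 4 (6) in the same order. Of the lists of this part 4 passed in the WT response (highest other 4), which is the most possible. For the interaction of these 4 lists chance cannot be excluded. Of 100 splits, drawn from 200 with the genotype and treatment effects taken out, 8 gave the real count of 4, the real split included. A count of 4 is the most that 4 lists can give, so no split could exceed it.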
